A study of Mus musculus with 12 samples.

How the data were processed

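Total RNA of whole mouse placenta at gestation day 12.5 was sequenced in 12 libraries, 6 from KO sires and 6 from WT sires, all from wildtype C57BL/6J dams. The deposited values are TPM (shares of transcripts, scaled for transcript length and to a fixed total), named by gene symbol or sequence record and UCSC transcript. Per the submitters' processing notes, kallisto 0.43.1 and build mm10 were used; kallisto assigns reads to transcripts without full alignment, and how it was run is not given in the sources used here. The deposited TPM of each library summed to between 948099 and 959664, and no row was 0 in all libraries. TPM are shares, so a rise of abundant transcripts lowers the rest, and they keep no depth: the depth per library is unknown, and no counting interval or detection limit can be given. Library strandedness is not given in the sources used here, so overlapping antisense genes cannot be told apart.

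The 46210 transcript rows were summed to 22483 genes, of which 13396 had a mean of at least 1 TPM over the 12 libraries and were tested. Names were matched to the GRCm38 annotation (the same assembly as mm10), which covered 12709 tested genes, 12113 of them protein-coding; transcript length was known for 94.6% of tested genes. Names without an annotated gene took between 6.79% and 14.2% of the TPM of a library. Mitochondrially encoded genes and several list members, among them Ptgs2, Il6 and Col1a1, were not analysed here.

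The groups came from the sample labels. Before the data were examined, a count test was planned on the premise of estimated counts, with limma on log values as the written fallback; as the values are TPM, the fallback was used throughout. limma 3.58.1 (R 4.3.3) was fitted to log2(TPM + 1) with an intensity trend in the variance, group as the only term and Benjamini-Hochberg adjustment at an FDR of 0.05; every adjusted p for a gene is from this fit. A fold change is on the log2(TPM + 1) scale, which understates the change of low genes. Errors of TPM are SD, and those of log2 fold changes are SE. The same steps were tested on simulated data for 13396 genes, 200 of them changed, with independent genes. There 70% of genes changed by 1 log2 unit and 91% of those changed by 2 passed. Of the calls 5.29% were false, and 0 of 30 unchanged lists were called. List members were correlated in the real libraries (estimated at 0.68 for the cell cycle list), so the simulation does not show the errors of a list test there. Splits of the real libraries other than by sire gave up to 22 lists.

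Of 36 gene lists fixed before the data were examined, 34 held at least 5 tested genes and were tested with limma's camera (preset correlation 0.01, adjusted over the 34 lists), and again with an estimated correlation and with fry, which tests each list without comparing it to other genes. Of 940 list entries 866 had a row, 20 of them by an older symbol. Mitochondrially encoded genes were the list without rows, and sex-linked genes were described only. A list score is the mean log2(TPM + 1) of its tested members. The named genes were chosen by a rule fixed at the same time: Rgs2; 8 preset genes; the 10 largest changes each way among passing genes with a mean of at least 1 TPM; and from each list up to 4 passing members by lowest p, or where none passed up to 2, as values only. The embryonic globins, Hbb-bs, Ddx3y, Xist, Afp and Kif21b were named outside this rule, after their values were seen.

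Single values were compared with exact two-sided permutation tests in scipy 1.17.1 (Python 3.11.15), for which 6 against 6 allow a smallest p of 0.00216. Alternatives covered scaling, filter, pseudocount, quality weights, a fold threshold of 1.2, covariates and each library left out. Added after the data were seen were a mean of at least 5 TPM, quantile normalization, protein-coding genes rescaled, a length and GC correction, and the natural killer and yolk sac marker means as covariates. For the length and GC correction, each library's deviations from the gene means were centred on their medians in bins of transcript length and of GC content.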

Results

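RNA sequencing was used to compare whole mouse placentas at gestation day 12.5 from pregnancies that differed in the sire. Rgs2 encodes a regulator of G protein signalling that shortens signalling through Gq-coupled receptors, such as those for angiotensin and vasopressin. C57BL/6J dams, all wildtype, had been mated with Rgs2 knockout sires, which gave Rgs2-heterozygous conceptuses (KO-sire placentas, libraries 1 to 6), or with wildtype littermates of those sires, which gave wildtype conceptuses (WT-sire placentas, libraries 7 to 12). Each group thus held 6 libraries, and the decidual and other maternal cells in every placenta were wildtype. Expression was available as TPM, length-scaled shares of transcripts, which keep no record of sequencing depth, so the depth of each library is unknown. The labels do not say that the placentas came from separate dams or litters, so the p-values measure only the spread between these samples. No libraries were identical, and the median Spearman correlation over genes was 0.948 within groups and 0.931 between them.

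The first comparison asked whether the targeted gene was lower in the placentas of KO sires. Rgs2 (chromosome 1, positions 143999338 to 144004161, minus strand, build GRCm38) averaged 4.59 ± 1.17 TPM (SD, n = 6) with KO sires and 8.74 ± 5.14 TPM (SD, n = 6) with WT sires. Its log2 fold change was -0.65 (SE 0.32), with a limma adjusted p of 0.183 and an exact two-sided permutation p of 0.0714 on the TPM values, so the difference did not pass. The KO-sire libraries lay between 3.15 and 6.15 TPM, and WT-sire libraries 9 and 11, at 3.38 and 3.81 TPM, lay within that range while library 8 reached 16.8 TPM. The mean of uterine natural killer cell markers varied alongside, with Rgs2 following it among the WT-sire libraries (Pearson r = 0.947, exact permutation p = 0.00833, n = 6). With that mean as a covariate the log2 difference of Rgs2 was 0.43, and with the decidua marker mean it was 0.06. Rgs2 thus did not by itself separate the labelled groups.

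**Figure D1:**
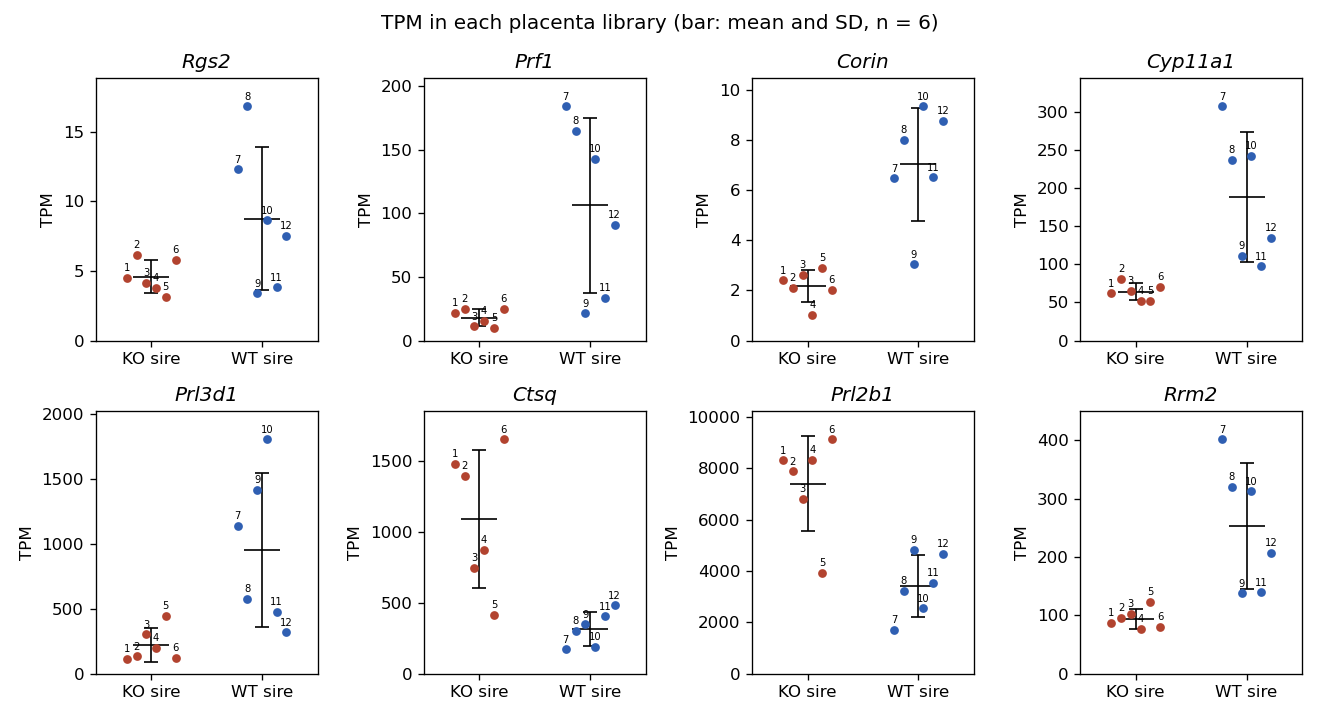
TPM of 8 genes in each placenta library, with library numbers beside the points and bars for the mean and SD of each group (n = 6); each vertical axis is linear and starts at 0. Rgs2 of WT-sire libraries 9 and 11 lies among the KO-sire values, while Corin lies between 3.05 and 9.34 TPM in all WT-sire libraries, above every KO-sire library.

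Ctsq, a cathepsin of trophoblast, rose from 315 ± 120 to 1091 ± 486 TPM with KO sires (SD, n = 6 each). Prl3d1, placental lactogen of trophoblast giant cells, fell from 954 ± 592 to 218 ± 133 TPM. Cyp11a1, which makes pregnenolone from cholesterol, fell from 188 ± 85.5 to 63.8 ± 11.1 TPM. Prf1, the perforin of cytotoxic lymphocytes, fell from 106 ± 68.6 to 18.03 ± 6.66 TPM. In all, 387 of 13396 genes passed an FDR of 0.05 in limma, 156 higher and 231 lower with KO sires, and 152 of them differed by at least 2-fold.

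The calls sat close to the threshold and depended on single libraries and on scaling. The lowest adjusted p was 0.0437, and 4127 genes had an unadjusted p under 0.05. Without KO-sire library 5 the count was 3402, without WT-sire library 9 it was 956 and without library 12 it was 649. It was 0 without KO-sire library 1, 3, 4 or 6 or WT-sire library 7 or 8, and 1 without library 2, 10 or 11. Of all tested genes 66.1% were lower with KO sires, and counts of lower list members are to be read against that share. The median log2 fold change of all genes was -0.14. It moved to -0.02 with median-of-ratios scaling, to 0.02 with quantile normalization and to -0.02 after a correction for transcript length and GC content. With these the share of passing genes that were higher was 57.8%, 69.4% and 58.3%, against 40.3% here, and it was 28.3% when protein-coding genes alone were rescaled. No gene passed with the decidua marker mean as a covariate (3311 at an unadjusted p under 0.05) or with the Y-linked mean as a covariate (3551 at an unadjusted p under 0.05), and 1 passed with the natural killer marker mean. Across genes, which are not independent replicates, the fold change fell with transcript length (Spearman's rho = -0.338), and its median ran from 0.03 in the shortest of 4 equal bins of genes to -0.31 in the longest.

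Among the genes with the largest upward fold changes, Cts6, another trophoblast cathepsin, rose by a log2 fold change of 4.05 (SE 0.86) from 2.29 ± 2.19 to 87.6 ± 81.5 TPM (SD, n = 6 each). The others with a symbol in current use were Gkn2 (2.60), Prl3a1 (2.34), the pepsinogen gene Pga5 (2.20), Prl8a6 (2.18), Creg1 (1.79) and Ctsq (1.74), all as log2 fold changes with adjusted p between 0.0437 and 0.0479. AK208648 and AB346293, named after sequence records, had log2 fold changes of 2.75 and 1.69. They were listed at 0 in every WT-sire library but library 12 (AK208648, 1.4 TPM) and library 9 (AB346293, 0.72 TPM). Their folds thus depend on the 1 TPM added before the logarithm. TRNA_Met, a transfer RNA entry, was listed at 0 in every WT-sire library and averaged 9.26 ± 5.39 TPM with KO sires, so no fold is given. Creg1 was abundant, at 2403 ± 895 TPM against 722 ± 400 TPM.

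Largest among the downward changes were those of the predicted genes Gm9513 and Gm7257, at log2 fold changes of -3.94 (SE 0.51) and -3.58 (SE 0.56), and of Mir186 at -3.31 (SE 0.48). Mir186 was listed at 0 in every KO-sire library but library 5 (4.88 TPM), so its fold depends on the 1 TPM added before the logarithm. Endou, a placental endoribonuclease, fell from 11.3 ± 7.42 to 1.08 ± 0.69 TPM (SD, n = 6 each). Further log2 fold changes were -2.27 for Doxl2, an amine oxidase family member, -2.20 for Prf1, -2.15 for the lymphocyte receptor Klrg1, -2.09 for the carotene oxygenase Bco1 and -2.09 for the AMP deaminase Ampd3. DQ725877, a sequence record, was listed at 0 in every KO-sire library and averaged 5.51 ± 3.72 TPM with WT sires.

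Preset placental genes for anti-angiogenic signalling and trophoblast lineages did not pass. Flt1, whose soluble form binds VEGF and placental growth factor, had a log2 fold change of 0.59 (SE 0.37, adjusted p = 0.283). Pgf, placental growth factor, was at -0.66 (SE 0.19, adjusted p = 0.0663), Eng at -0.67 (SE 0.21, adjusted p = 0.0745) and Vegfa at 0.07 (SE 0.15, adjusted p = 0.745). Hdac9, a histone deacetylase near the floor at 0.60 ± 0.19 against 2.19 ± 1.23 TPM, was at -0.91 (adjusted p = 0.0599). The spongiotrophoblast gene Tpbpa was at 1.16 (SE 0.33, adjusted p = 0.0651), placental lactogen Prl3b1 at 0.29 (adjusted p = 0.2495) and the decidual prolactin Prl8a2 at -1.31 (adjusted p = 0.110).

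The next comparison asked which of 34 gene lists, fixed before the data were examined, stood apart from the other genes. By limma's camera test with a preset correlation, the lists of pregnancy-specific glycoproteins and placental cathepsins stood above them and those of cell cycle genes and uterine natural killer cells below. With an estimated correlation these calls were lost (adjusted p = 0.888 with an estimated correlation for the cathepsins, glycoproteins and natural killer markers, and adjusted p = 0.893 with an estimated correlation for the cell cycle), and none passed by the rotation test fry. The pregnancy-specific glycoproteins, secreted proteins of spongiotrophoblast, had a median 1.68 log2 units above that of all genes, and the uterine natural killer markers had one 1.55 log2 units below it (median difference -1.55). With the preset correlation 15 lists passed, 9 above and 6 below, and none of the 15 passed with an estimated correlation or by fry.

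**Figure D2:**
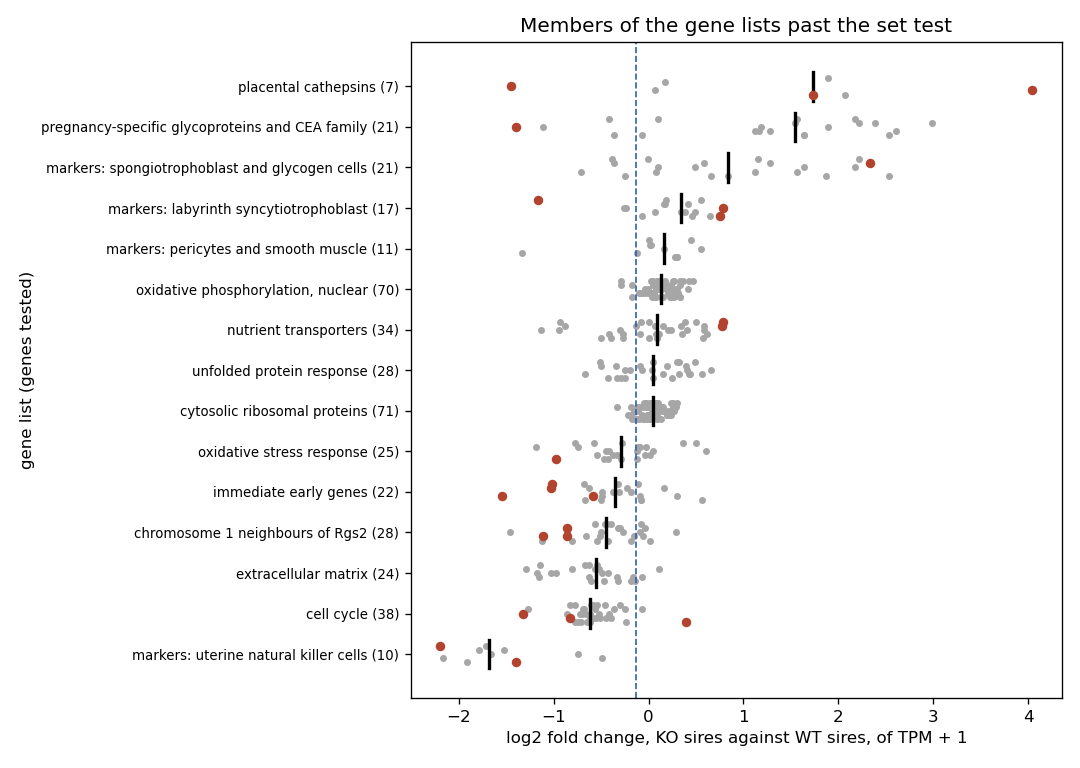
Log2 fold changes of TPM + 1 for the tested members of the 15 lists past camera's test, KO sires against WT sires, with 1 point per gene and the number tested in parentheses. Large dark red points passed the FDR of 0.05 over all genes, black bars are list medians and the dashed line is the median of all genes at -0.14; the glycoprotein median lies at 1.55 and the natural killer median at -1.69.

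Pregnancy-specific glycoprotein and related genes were higher in 16 of 21 tested members (camera adjusted p = 7.9e-07; adjusted p = 0.888 with an estimated correlation). Of these genes 1, Psg20, passed over all genes, and it fell, by a log2 fold change of -1.40; adjusted over the list alone, 15 rose and 3 fell. The placental cathepsins had 2 risers, Ctsq and Cts6, and Cts7 fell from 3.94 ± 2.76 to 0.63 ± 0.35 TPM; adjusted over the list alone, 4 of 7 rose and 1 fell (camera adjusted p = 0.00320; adjusted p = 0.888 with an estimated correlation). Under quantile normalization and the length and GC correction the camera adjusted p of the cathepsins was 0.0679 and 0.0593, with medians 1.69 and 1.70 above all genes. The difference of their library score from the median gene was 1.42 (SE 0.39) before and 1.23 (SE 0.36) after that correction. Without a filter on low genes the median of the cathepsins less that of all genes was 0.22 in place of 1.87. Spongiotrophoblast and glycogen cell markers, 13 of whose 21 members stand on other lists too, had 1 riser, Prl3a1, and 13 adjusted over the list alone (camera adjusted p = 4.4e-07; adjusted p = 0.888 with an estimated correlation). These families hold near-identical paralogs among which reads can be split, so values of single members are uncertain. Beside them, the ratio of embryonic to adult beta-globin (Hbb-bh1 to Hbb-bs) had a log2 mean of -4.56 ± 2.58 with KO sires and -1.83 ± 0.39 with WT sires (exact permutation p = 0.0390), with KO-sire library 5 at -0.26.

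Prolactin family genes moved both ways. Prl2b1 rose from 3416 ± 1206 to 7401 ± 1862 TPM, as did Prl3a1 and Prl8a6, and Prl3d1 fell; 3 rose, 1 fell and 18 did not pass, with 6 up and 10 down adjusted over the list alone (camera adjusted p = 0.993). Trophoblast giant cell markers, 9 of 12 shared with other lists, had Ctsq up and Cts7 and Prl3d1 down, and 3 up and 7 down adjusted over the list alone (camera adjusted p = 0.523). Labyrinth syncytiotrophoblast markers stood above other genes by 0.48, or by 0.32 without a filter (camera adjusted p = 0.00364; adjusted p = 0.893 with an estimated correlation). Ovol2, a regulator of labyrinth trophoblast, rose by 0.75 and the lactate transporter Slc16a3 by 0.79, and the receptor Met fell, at -1.17; 2 rose and 1 fell adjusted over the list alone too. Nutrient transporters had 2 risers, Slc16a3 and the fatty acid binding protein Fabp3, which went from 830 ± 249 to 1399 ± 273 TPM; adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.0116; adjusted p = 0.893 with an estimated correlation; camera adjusted p = 0.0546 with quantile normalization). Their median less that of all genes was 0.22, and it was 0.20 with quantile normalization and 0.14 without a filter. Of 37 imprinted genes Slc22a18 rose by 0.94, and 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.936).

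Steroid genes fell in 3 of 20 cases and rose in 1. Cyp11a1 fell by 1.43 on the log2 scale, Cyp17a1 by 0.77 and Star, which carries cholesterol into mitochondria, by 1.26, while Hsd11b2, which inactivates glucocorticoids, rose by 0.88. Adjusted over the list alone 8 fell and 1 rose, and the list did not pass (camera adjusted p = 0.149). Cyp11a1 was highest in WT-sire libraries 7, 8 and 10 (307, 237 and 242 TPM), which also had the highest natural killer marker means (7.39, 7.23 and 7.02 log2(TPM + 1)). Cyp17a1 and Star did not keep that order. They were highest in library 10 (118 and 99.6 TPM). In library 9, with the lowest natural killer mean of the WT-sire group (4.89), they were at 98.0 and 77.6 TPM, against 82.0 and 62.1 TPM in library 8. Vasoactive peptide genes fell in 4 of 21 cases. Corin, the protease that activates atrial natriuretic peptide, fell from 7.02 ± 2.27 to 2.18 ± 0.65 TPM, adrenomedullin (Adm) from 104 ± 50.7 to 36.9 ± 14.98 TPM, its receptor gene Calcrl from 8.36 ± 3.37 to 2.91 ± 0.44 TPM and the natriuretic peptide receptor Npr2 from 10.0 ± 3.74 to 4.19 ± 0.79 TPM (SD, n = 6 each). That list had 9 down and 1 up adjusted over the list alone (camera adjusted p = 0.0960). With the natural killer marker mean as a covariate, the medians of the steroid and vasoactive lists less that of all genes went from -0.54 and -0.46 to 0.0456 and 0.0406. Angpt2, a vascular destabilising factor, fell by 1.09 and was the sole passing member among 18 angiogenic genes, of which 5 fell adjusted over the list alone (camera adjusted p = 0.262).

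Markers of maternal cells had lower library means with KO sires. All 10 tested uterine natural killer markers had negative fold changes, Prf1 and the T-box factor Eomes (log2 fold change -1.39, SE 0.21) passed, and 9 fell adjusted over the list alone (camera adjusted p = 2.1e-04; adjusted p = 0.888 with an estimated correlation). With the decidua marker mean as a covariate the list's median less that of all genes went from -1.55 to -0.32 and the call was lost (camera adjusted p = 0.0545). It was -0.83 without a filter. Of 18 decidua markers Hand2 fell by 1.77, Angpt2 by 1.09, Errfi1 by 0.92 and Bmp8a by 0.89 on the log2 scale; adjusted over the list alone 10 fell and 2 rose (camera adjusted p = 0.0573). With the natural killer marker mean as a covariate the decidua median lay 0.39 above all genes (camera adjusted p = 0.0188). Library means of the natural killer markers were 4.84 ± 0.45 with KO sires and 6.396 ± 1.07 log2(TPM + 1) with WT sires (exact permutation p = 0.0195), and those of decidua 4.49 ± 0.31 and 5.13 ± 0.59 (exact permutation p = 0.0498). WT-sire libraries 9 and 11 had natural killer means of 4.89 and 5.25, inside the KO-sire range of 4.20 to 5.26. Eomes did not follow that mean throughout. It was highest in WT-sire libraries 7, 8 and 10, but at 5.47 and 5.01 TPM in libraries 9 and 11 it lay above every KO-sire library (1.07 to 2.73 TPM). KO-sire libraries 3 and 5, with the lowest natural killer means (4.41 and 4.20), had the highest Eomes of their group.

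Cell cycle genes were lower in 37 of 38 cases (camera adjusted p = 7.9e-07; adjusted p = 0.893 with an estimated correlation). The ribonucleotide reductase genes Rrm2 and Rrm1 fell by 1.32 and 0.83 on the log2 scale, and Pttg1 (securin), whose product inhibits separase and so delays the separation of sister chromatids, rose by 0.40; 30 fell and 1 rose adjusted over the list alone. With the natural killer marker mean as a covariate the list's median less that of all genes went from -0.48 to -0.75. KO-sire library 5, which had the highest globin ratio of its group, had a cell cycle score of 5.34 log2(TPM + 1), above every WT-sire library (4.82 to 5.31), while the other KO-sire libraries lay between 4.03 and 4.67. Immediate early genes had 4 that fell, the AP-1 members Fos (-1.02) and Fosl1 (-1.54), with Maff (-0.59) and Ier3 (-1.03), and 10 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0126; adjusted p = 0.893 with an estimated correlation). Gsr, glutathione reductase, fell by 0.98 in the oxidative stress list, where 13 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.0399; adjusted p = 0.893 with an estimated correlation). Extracellular matrix genes were lower in 23 of 24 cases with none passing over all genes, and 5 fell adjusted over the list alone (camera adjusted p = 0.0127; adjusted p = 0.893 with an estimated correlation). The medians of the immediate early, oxidative stress and matrix lists came closer to that of all genes with the maternal marker means as covariates. With the decidua marker mean as a covariate their medians less that of all genes went from -0.21, -0.16 and -0.42 to -0.0460, -0.0351 and -0.23 (camera adjusted p = 0.242, 0.426 and 0.736). With the natural killer marker mean they went to -0.0457, -0.0410 and -0.29 (camera adjusted p = 0.501, 0.802 and 0.802). Whether these lists followed the maternal markers within groups was not tested. KO-sire library 5 had the lowest natural killer mean of its group (4.20) but the highest matrix (5.18) and oxidative stress (6.64) means. The immediate early call was also lost with quality weights (camera adjusted p = 0.104), where the list's median less that of all genes was still -0.20. The oxidative stress call was also lost with median-of-ratios scaling (camera adjusted p = 0.0704), the Y-linked covariate (0.0759) and the yolk sac covariate (0.0795). There the list's median less that of all genes was -0.14, -0.13 and -0.15. It was -0.24 without a filter, -0.24 with quantile normalization and -0.25 after the length and GC correction, all with the call kept. In the matrix list the values nearest to passing were -1.18 for Fbn1 (adjusted p = 0.0561) and -0.63 for Lama5 (adjusted p = 0.0663).

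Nuclear genes of oxidative phosphorylation were higher in 59 of 70 cases, by a median of 0.13, or 0.27 above all genes, and none passed singly or adjusted over the list alone (camera adjusted p = 2.9e-10; adjusted p = 0.888 with an estimated correlation). After the length and GC correction the list's median less that of all genes was 0.0797, and with quantile normalization it was 0.15, both with the call kept. Uqcr10 was at 0.42 (adjusted p = 0.0802) and Ndufv2 at 0.29 (adjusted p = 0.0742). Ribosomal protein genes had a median 0.18 above all genes (camera adjusted p = 0.0114; adjusted p = 0.998 with an estimated correlation), but -0.03 relative to all genes after the length and GC correction and -0.02 with quantile normalization, and 0.0979 without a filter. The ribosomal call was also lost with quality weights (camera adjusted p = 0.577), the Y-linked covariate (0.127) and the decidua covariate (0.170). With these the list's median was 0.0991, 0.15 and 0.16 above all genes. Rpl29 and Rpl28 were at -0.21 and -0.17, and none passed in either count, that adjusted over the list alone included. Unfolded protein response genes lay 0.19 above all genes (camera adjusted p = 0.0444; adjusted p = 0.906 with an estimated correlation), with Creld2 at 0.65 (adjusted p = 0.0507) and Herpud1 at -0.51 (adjusted p = 0.0581). Adjusted over the list alone 2 rose and 1 fell. The list's median less that of all genes was 0.0994 without a filter and 0.30 with quality weights. The call ended without a filter (camera adjusted p = 0.0766), with the decidua (0.10004), natural killer (0.295) and yolk sac (0.0697) covariates, with quantile normalization (0.467) and after the length and GC correction (0.0543). With those covariates the list's median less that of all genes was still 0.18, 0.17 and 0.18. It was 0.13 with quantile normalization and 0.25 after the length and GC correction. Pericyte and smooth muscle markers lay 0.30 above all genes (camera adjusted p = 0.0263; adjusted p = 0.893 with an estimated correlation), with Myl9 at 0.44 and Acta2 at 0.28 and none passing, also adjusted over the list alone. The list's median less that of all genes was 0.0734 without a filter, 0.46 with quality weights and 0.49 with the natural killer covariate. With quantile normalization it was 0.31, though the call was lost (camera adjusted p = 0.0675). Ribosomal and respiratory chain proteins are mostly small and their transcripts short, and in KO-sire library 4 the median gene stood at 3.44 log2(TPM + 1), below the 3.66 to 3.97 of the other KO-sire libraries.

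Genes that neighbour Rgs2 on chromosome 1 were lower in 26 of 28 cases, where 66.1% of all tested genes were lower (camera adjusted p = 0.00127, and adjusted p = 0.888 with an estimated correlation). Rgs16 (chromosome 1, positions 153740349 to 153745468, plus strand), another regulator of G protein signalling, fell from 23.8 ± 4.63 to 12.6 ± 2.63 TPM, Lamc2, a laminin chain, fell by 1.11 and Fam129a by 0.87 on the log2 scale; 11 fell adjusted over the list alone. In the RGS family list, Rgs16 was the sole passing gene of 9, also adjusted over the list alone (camera adjusted p = 0.992). Gq-coupled receptors and effectors did not pass (camera adjusted p = 0.632): Ptger1 was at -0.61 (adjusted p = 0.0667) and Ednrb at -0.50 (adjusted p = 0.0719), and 2 of 14 fell adjusted over the list alone.

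Further lists did not pass. Camera adjusted p was 0.824 for hypoxia response (Serpine1 at -0.58, Hk2 at -0.72), 0.993 for interferon response (Ifit2 at -1.16, Bst2 at 0.60), 0.936 for inflammatory cytokines (Cxcl12 at 1.43, Il1a at -0.43) and 0.992 for histone deacetylases (Hdac3 at 0.23). Among cell type markers it was 0.824 for macrophages (Ptprc at -1.13, Cd14 at -0.75), 0.992 for neutrophils and platelets (S100a8 at -1.31, Gp1bb at 0.45), 0.564 for endothelium (Pecam1 at -0.77, Cldn5 at -0.80), 0.993 for yolk sac (Lrp2 at -1.14, Cubn at -1.56) and 0.993 for uterine epithelium and myometrium (Epcam at -0.23, Actg2 at -0.59). None of those members passed over all genes; adjusted over the list alone, 1 cytokine, 1 endothelial and 1 neutrophil or platelet gene rose, and 1 deacetylase, 4 endothelial and 1 neutrophil or platelet gene fell. Erythroid markers did not pass as a list (camera adjusted p = 0.936), and adult alpha-globin Hba-a2 rose from 9683 ± 3127 to 16450 ± 1773 TPM, the sole passing member by both counts, that adjusted over the list alone included. With the decidua marker mean as a covariate the cytokine and macrophage medians lay 0.36 and 0.37 above all genes (camera adjusted p = 0.0120 and 0.0433), and with the natural killer marker mean 0.95 and 0.56 above (camera adjusted p = 3.2e-04 and 0.00132). The interferon response list also passed with the same 2 covariates, with its median 0.33 and 0.51 above all genes. In the cytokine, imprinted, erythroid, yolk sac and uterine epithelium lists the median and camera's direction differed in sign, with medians below that of all genes.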

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

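Apart from camera, which was planned, the tests weighed in this part were chosen after the results were seen. Among 254 sets of 6 libraries, each a named gene or list mean within a group, 42 values stood apart from the other 5 by more than 0.625 of the range, Dixon's bound; chance gives about 1 in 20. KO-sire library 4 accounted for 18, KO-sire library 5 for 7, WT-sire library 9 for 5 and WT-sire library 12 for 4. All values here are log2(TPM + 1).

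KO-sire library 5 was the lowest of its group for Tpbpa (13.16 against 14.40 to 14.69), Prl3b1 (13.82), Prl2b1 (11.94) and Creg1 (9.59), and the highest for Met (2.06), Gsr (4.86) and Mir186 (2.56, with the others at 0). WT-sire library 9 was high for Prl3b1 (14.67) and AB346293 (0.79), and low for Corin (2.02), DQ725877 (listed at 0) and the renin-angiotensin and vasoactive peptide mean (2.72). WT-sire library 12 was high for AK208648 (1.27), Prl3a1 (0.70) and Ovol2 (4.74) and low for Fam129a (4.70). In other libraries, TRNA_Met was listed at 0 in KO-sire library 2, Herpud1 was at 6.01 in KO-sire library 6, Actg2 at 3.37 in KO-sire library 1 and at 4.78 in WT-sire library 8, Il1a at 3.40 in WT-sire library 8 and Gp1bb at 2.89 in WT-sire library 7. The ribosomal protein mean was 9.84 in WT-sire library 11, and the sex-linked mean was 0.96 in KO-sire library 3.

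KO-sire library 4 was low for Rgs16 (3.11), Hk2 (2.82), Ier3 (4.62), Errfi1 (5.45), Gp1bb (3.75) and Lamc2 (1.70) and high for Ndufv2 (7.07). Its means were low for Gq-coupled receptors (3.20), the RGS family (3.06), angiogenic factors (3.89), hypoxia response (5.33), immediate early genes (3.86), endothelium (4.05), labyrinth syncytiotrophoblast (4.86), nutrient transporters (4.84) and steroid metabolism (4.41), and high for ribosomal proteins (10.44) and oxidative phosphorylation (7.99). The median gene of this library was also the lowest of its group (3.44), so these values are not independent of one another. Relative to the median gene its RGS family score was -0.37, inside the range of the other KO-sire libraries (-0.74 to -0.37).

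By camera's preset correlation oxidative phosphorylation and ribosomal protein genes lay high, and cell cycle genes low, against other genes with KO sires (adjusted p = 0.888, 0.998 and 0.893 with an estimated correlation), and a trend with transcript length and GC content between libraries is a candidate explanation. For the cell cycle genes the difference of the library scores from the median gene was -0.39 before correction for length and GC and -0.40 after (exact permutation p = 0.0411, and 0.00433 to 0.0823 with a library left out), which argues against the trend as the cause of that part. For the ribosomal proteins it was 0.24 before (exact permutation p = 0.149) and 0.0199 after (exact permutation p = 0.766), as the trend would give, but the first lay within the spread between libraries and was 0.11 without KO-sire library 4, whose score went from 7.00 to 6.32. For oxidative phosphorylation it was 0.34 before (exact permutation p = 0.0108), or 0.22 without KO-sire library 4, and 0.14 after, with 40.9% left. The exact permutation p after correction was 0.00216, the smallest that 6 against 6 allow, and 0.00433 with any library left out. Every corrected KO-sire score (lowest 3.75) lay above every WT-sire score (highest 3.71). The trend may thus account for most of the difference. What was left does not decide whether the trend is its whole cause. The correction used lengths from the annotation, not those of the deposited transcripts, and may be incomplete. A difference by sire genotype stays open and was not tested.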

How the results depend on the processing

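Tests added after the data were seen are a mean of at least 5 TPM, quantile normalization, protein-coding genes only, the length and GC correction and the natural killer and yolk sac covariates. Of the planned ones, the count-based tests and their normalization and filter were not run, as they need counts. Lists have no value of their own under the fold threshold, nor a list under its own mean as covariate. No paired analysis was possible because library numbers run from 1 to 12 across the groups and are not shared. The cause of a change was not tested unless stated. Depth is unknown, so what it limits cannot be given.

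Against 387 genes, the count was 820 with median-of-ratios factors, 0 without a filter (more genes tested; 5139 at an unadjusted p under 0.05), 5511 with quality weights, 0 with a fold threshold of 1.2 (1297 at an unadjusted p under 0.05 in its own, stricter test), 0 with the Y-linked covariate (3551) and 0 with the decidua covariate (3311), 1522 with the first residual component, 960 with quantile normalization, 629 with protein-coding genes only, 909 after the length and GC correction, 1 with the natural killer covariate and 2 with the yolk sac covariate; it was 369 and 383 with pseudocounts of 0.1 and 0.5, 399 without erythroid and sex-linked genes (49.4% higher) and 359 at 5 TPM. Leaving out each library gave 0 to 3402. The 387 genes were all among the 5511, the 1522 and the 3402 without KO-sire library 5. The 15 lists became 0 with an estimated correlation and 0 with fry, and 12 to 15 lists passed with a library left out. Of the 15, those still passing were 9 with the decidua covariate, 10 with the natural killer covariate (the natural killer list being its own covariate there), 10 with quantile normalization, 12 after the length and GC correction, 13 each with quality weights and the Y-linked and yolk sac covariates, and 14 each with median-of-ratios factors and without a filter. Rgs2 went from -0.65 to 0.0596 with the decidua covariate and 0.43 with the natural killer covariate, and ran from -0.85 to -0.44 with a library left out; it passed in none of these.

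Of the other values for named genes and lists outside the left-out libraries, 1495 kept direction and side of the threshold, 384 no longer passed, 92 passed newly and 32 changed direction. Those that changed direction (list medians less that of all genes) were as follows. Without a filter: RGS family -0.0472, Gq-coupled 0.00856, interferon -0.0639. Uterine epithelium: 0.0803 and 0.00807 with pseudocounts 0.1 and 0.5, 0.0718 with the Y-linked, 0.0771 with the decidua, 0.18 with the natural killer and 0.0742 with the yolk sac covariate. Decidua covariate: hypoxia 0.00890, cytokines 0.36, macrophages 0.37, endothelium 0.0671. At 5 TPM: RGS family -0.0306, Gq-coupled 0.00403, erythroid 0.15. Quantile: ribosomal -0.0174, deacetylases 0.00355. Length and GC: RGS family -0.0840, ribosomal -0.0311. Natural killer covariate: Prl8a2 0.11, Ptprc 0.0737, S100a8 0.00788, Actg2 0.00992, vasoactive peptides 0.0406, hypoxia 0.0343, cytokines 0.95, steroid 0.0456, decidua 0.39, macrophages 0.56, neutrophils and platelets 0.0858, endothelium 0.17. Of these, the calls gained by camera (adjusted p) were cytokines (0.0120) and macrophages (0.0433) with the decidua covariate, and cytokines (3.2e-04), macrophages (0.00132) and decidua (0.0188) with the natural killer covariate; none of the others passed. With a library left out, 937 kept both, 505 no longer passed, 40 passed newly and 18 list values changed direction, within -0.0834 to 0.15 for interferon, -0.0741 to 0.00681 for deacetylases, -0.0598 to 0.0179 for imprinted genes, -0.25 to 0.12 for macrophages, -1.67 to 0.0585 for yolk sac and -0.15 to 0.10 for uterine epithelium.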

Other observations

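Apart from limma, camera and fry, which were planned, and the splits of the libraries, the tests in this part were chosen after the results were seen. The embryonic globins Hbb-bh1 and Hba-x differed between the placentas in a way that the lists did not describe, while the level of Hbb-y was not lower with KO sires. Hbb-bh1, an embryonic beta-globin of primitive red cells, was between 81.6 and 106 TPM in KO-sire libraries 1, 2 and 6. It was at 428 and 754 TPM in libraries 3 and 4, and at 2458 TPM in library 5. In WT-sire libraries it lay between 687 and 3099 TPM. The log2 ratio of embryonic to adult alpha-globin, Hba-x to Hba-a2, averaged -2.49 ± 1.30 with KO sires and -0.75 ± 0.23 with WT sires (n = 6 each, exact permutation p = 0.0152). Hbb-y, another embryonic beta-globin, was not lower with KO sires, at 4241 to 13966 TPM against 3500 to 8282 TPM with WT sires. Among the KO-sire libraries it was lowest in 1, 2 and 6 (5583, 4241 and 6171 TPM) and highest in 5, as were Hbb-bh1 and Hba-x. Neither the level of Hbb-y nor its ratio to Hbb-bs was tested.

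Yolk sac transcripts varied widely within both groups. Afp, alpha-fetoprotein of visceral endoderm, ranged from 13.9 to 6973 TPM with KO sires and from 1.41 to 12928 TPM with WT sires (means 2230 and 4746 TPM, exact permutation p = 0.333), and all 14 tested yolk sac markers had negative fold changes (median -0.70), so a difference was neither shown nor excluded. Ddx3y, a Y-linked gene, was under 0.5 TPM in KO-sire library 3 and in 3 WT-sire libraries (7, 11 and 12), and at least 8.77 TPM in the others. Xist, of the inactive X chromosome, was at least 11.1 TPM in those 4 libraries and at most 4.15 TPM in the others. By these genes fetal sex was not balanced between the groups, though the Y-linked mean did not differ beyond its spread (difference 0.70, SE 0.79, exact permutation p = 0.539). What the loss of all calls with the Y-linked covariate owes to sex was not tested.

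Against other splits of the 12 libraries, the count of genes was high and the count of lists was not. The real split gave 387 genes and the highest of the 99 others gave 52. Of 100 splits, drawn from 462 possible, only the real one gave as many. The labels do not show separate dams or litters, so the splits cannot tell a difference by sire from one between litters. The count of genes also depended on single libraries, as given above. For lists the real split gave 15 and the highest other gave 22, and 23 of 100 splits gave as many.

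By camera's preset correlation the glycoprotein, cathepsin and spongiotrophoblast lists lay above other genes and the cell cycle list below with KO sires (adjusted p = 0.888 for the first 3 and 0.893 for the last with an estimated correlation, and none passed by fry), and Prl3d1 fell. If all fetal layers were dissected alike, a smaller maternal share of the dissected tissue would raise fetal markers alike. The glycoprotein score exceeded the labyrinth score by 0.96 more with KO sires (SE 0.35, exact permutation p = 0.0173). The glycoprotein list was picked for this after its rise was seen, so the comparison does not decide against a smaller maternal share. A later stage of development at collection may account for the pattern. The log2 ratio of Hbb-bh1 to Hbb-bs was lower by more than its error (difference -2.73, SE 1.07, exact permutation p = 0.0390). The level of Hbb-y was not lower with KO sires (4241 to 13966 TPM against 3500 to 8282 TPM). Its ratio to Hbb-bs was not tested, and a level set beside a ratio does not decide for or against a later stage. KO-sire library 5, with the highest Hbb-bh1 to Hbb-bs ratio of its group, had the lowest glycoprotein score of its group (8.19). Within groups the relation was not established: over KO-sire libraries r was -0.898 (exact permutation p = 0.0611, adjusted 0.0917; rho = -0.714, p = 0.136, adjusted 0.204) and -0.526 without the 2 libraries farthest in ratio, and over WT-sire libraries r was -0.530 (exact permutation p = 0.331, adjusted 0.331; rho = -0.143, p = 0.803, adjusted 0.803) and 0.459 without the 2 farthest. An effect of the sire's genotype, on the pace of development or otherwise, stays open and untested.

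Rgs2 was lower with KO sires without passing, and a smaller maternal share of the tissue is a candidate explanation, since maternal cells carry 2 wildtype alleles. Among the 6 WT-sire libraries Rgs2 followed the natural killer score with r = 0.947 (exact permutation p = 0.00833, adjusted 0.0250 over 6 relations; rho = 0.943, p = 0.0167, adjusted 0.05), and r was 0.780 without the 2 libraries farthest in score. Among the KO-sire libraries r was 0.874 (exact permutation p = 0.0222, adjusted 0.0444; rho = 0.886, p = 0.0333, adjusted 0.0667), and 0.979 without the 2 farthest. With the score as a covariate the log2 difference went from -0.65 to 0.43, so its sign depended on that covariate. The loss of 1 fetal allele stays open, as whole tissue does not separate fetal from maternal transcripts.

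The natural killer and decidua scores followed each other among WT-sire libraries (r = 0.977, exact permutation p = 0.00556, adjusted 0.0250; rho = 0.943, p = 0.0167, adjusted 0.05; 0.809 without the 2 farthest). Among KO-sire libraries r was 0.758 (exact permutation p = 0.125, adjusted 0.150; rho = 0.657, p = 0.175, adjusted 0.210; 0.867 without the 2 farthest). The difference between these correlations was not tested.

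Genes near the targeted allele could carry variants of another strain that came along with it. Within 10 Mb of Rgs2, 4 of 66 genes passed (6.06%: Fam129a, Kif21b, Lamc2 and Rgs16, of which Kif21b was named after its value was seen), against 2.83% of 12643 elsewhere. The median log2 fold change of those 66 genes was -0.31, against -0.14 for all tested genes. The odds ratio was 2.21 (Fisher's exact p = 0.119), so an excess was not shown and none of that kind can be excluded.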
